A study of Mus musculus with 4 samples.

How the data were processed

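Whole cerebella of mice at postnatal days 10 and 14 were dissociated by the authors and profiled with droplet-based single-cell RNA sequencing, with 1 library each for WT and Eftud2 cKO at each age. Per the labels the meninges were removed, the tissue was treated with trypsin and the suspension was filtered. The deposited matrices hold counts, which are UMIs per gene and cell barcode, with no normalization. The submitters' processing notes name Cell Ranger 3.0.2, Seurat 4.1.3 and the mm10 build, whereas the matrices were written by Cell Ranger 5.0.0 (P10 WT), 7.0.1 (P10 cKO) and 7.1.0 (both P14 libraries), per the file headers. Whether intronic reads were counted is not stated. The long-read data named in the series title were not analysed here. The labels give no replicate numbers, no sex, no Cre line and no deleted exon.

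Gene coordinates came from GENCODE vM21 (GRCm38), to which 32235 of 32285 gene IDs were matched. Barcodes with fewer than 500 genes (2301, 104, 401 and 940 in P10 WT, P10 cKO, P14 WT and P14 cKO) and then those with over 20% mitochondrial UMIs (259, 46, 142 and 117) were left out, which kept 14280, 6593, 15395 and 6308 cells. Doublets were scored by Scrublet within Scanpy 1.11.5. Its automatic threshold called 0 doublets in 2 libraries, so 1 score threshold of 0.2196 was used for all, a choice made after this was seen. It removed 557, 176, 519 and 160 cells, or 3.90%, 2.67%, 3.37% and 2.54%.

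Cells were clustered jointly, without batch correction, on 2500 variable genes, 40 principal components, 20 neighbours and Leiden resolution 1 (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, seed 1), which gave 47 clusters. Called doublets were clustered with the rest and left out of all values. A cluster took the name of the class with the largest share of its markers, out of 153, detected: at least 3 markers, each with a UMI in 25% of the cells and over 2 times the level of other clusters after 5 CPM were added. Clusters mostly of doublets, with markers of more than 1 class, or with few UMIs and no marker among their leading genes were left unnamed, and the part of this rule on leading genes was refined after a border macrophage cluster had been seen. In all, 37 clusters were named and 10 were not, for 14 classes, of which 10 had at least 20 cells in each library and were compared. A second definition took as Purkinje-like any cell with UMIs of at least 5 of 11 Purkinje markers.

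UMIs were summed over the cells of a class in a library and divided by their total. Log2 ratios had 0.5 UMI added, exact Poisson intervals were used for sums and exact binomial intervals for shares, all at 95%, and these hold counting error only. A count of 0 was given an upper limit of 3 counts. For shares of cells with an Eftud2 UMI each cell was thinned to 2000 UMIs. For 25 gene lists the median ratio of members with at least 20 UMIs was set beside 10000 random lists matched on expression, as a description and not as a test. Of 947 list medians, 85 had a member at 0, and 39 differed when such members were set to a floor of 3 counts, a step added later. Intron length trends were taken over 20 bins of genes with introns and 1 bin without, with at least 50 genes per bin and 50 UMIs per gene. Tables and intervals were made with Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3, and figures with matplotlib 3.10.9.

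With 1 library per group there is no test of genotype at a single age. The genotype effect over both ages was fitted per class in edgeR 4.0.16 (R 4.3.3) with terms for age and genotype, TMM factors, filterByExpr at a minimum count of 10, the quasi-likelihood F test and adjusted p of 0.05, leaving 1 residual degree of freedom. DESeq2 1.42.0 was the other tool. The fits were tested on simulated data with a dispersion of 0.05 and 200 changed genes: edgeR recovered 70% to 96% of 4-fold changes with at most 8 false calls, and DESeq2 32% to 76% with at most 1. The fitted dispersions were higher, at 0.103 to 0.263, so the simulation was repeated at each class's own value after the fits had been seen: edgeR then recovered 0% to 45% of 4-fold changes with at most 1 false call, and DESeq2 0% to 33% with at most 12. The list medians were tested on simulated data as well, where the largest error was 0.023 without a trend and 0.035 with one, intervals covered 95.6% and 95.9% of true values, and 2.5% and 6.5% of unchanged lists fell outside the random range.

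Classes, markers, lists, filters, fits and most alternatives were chosen before the data were examined. Genes are named by a rule fixed at that time: per class the 5 highest and 5 lowest by the smaller absolute log2 ratio over both ages, without mitochondrial, sex-linked, haemoglobin and ribosomal protein genes, Malat1, or genes that moved alike in granule neurons; up to 4 members per list; up to 10 genes per fit; and always Eftud2, Pcp2, Calb1, Scd1, Gch1, Trp53, Cdkn1a, Atf4 and Shh. Only some of the genes that this rule gave are named below, and the rule did not fix which. Members of the lists that belong to a class (in astroglia, microglia, oligodendrocytes and progenitors) and Ttr, Dcc, Xist, Uty and Ddx3y are named as well, and were picked after their values were seen.

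The lists were the U5 and tri-snRNP spliceosome, p53 targets, ATF4 and integrated stress response targets, ferroptosis and iron handling, fatty acid desaturation and tetrahydrobiopterin, cholesterol synthesis, Purkinje synapse and calcium signalling, zebrin II type and zebrin II negative type Purkinje genes, Purkinje secreted signals, Shh response, cell cycle, early and mature granule neuron, disease-associated and homeostatic microglia, interferon response, reactive astroglia, Bergmann glia, myelin, hypoxia response, immediate early and dissociation genes, mitochondrially encoded, sex-linked and haemoglobin genes. The alternatives chosen at the start were at least 1000 genes per cell, at most 10% mitochondrial UMIs, doublets kept, each library clustered on its own (32, 28, 33 and 31 clusters), Leiden resolution 2 (65 clusters), TMM factors, means of per-cell CPM, thinning, subtraction of the granule neuron profile, members with at least 5 UMIs, DESeq2 size factors, no low-count filter and DESeq2. Those meant for Purkinje-like cells were applied to other classes, since no Purkinje-like class existed. Removal of the intron length trend, equal cluster weights, leaving out cluster 10 or 11 and a ranking at P14 alone were added after the data were seen.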

Results

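Whole cerebella of mice labelled Eftud2 cKO and of wild-type (WT) mice were profiled by droplet-based single-cell RNA sequencing at postnatal days 10 and 14 (P10 and P14), with 1 library per genotype and age. Eftud2 encodes a GTPase of the U5 small nuclear ribonucleoprotein, part of the core of the spliceosome. The series title names Purkinje cells, the output neurons of the cerebellar cortex, as the deficient cells. The libraries of P10 WT, P10 cKO, P14 WT and P14 cKO held 16691, 6719, 15837 and 7281 barcodes with 158017834, 92315263, 145731767 and 91091692 unique molecular identifiers (UMIs). After filtering, 13723, 6417, 14876 and 6148 cells remained, with medians of 8325, 10872, 7699 and 12209 UMIs and 2988, 3900, 3134 and 4091 genes per cell. With 1 library per group, no difference at a given age had a replicate check, and intervals below are 95% intervals for counting error only. Levels are CPM, the UMIs of a gene summed over the cells of a class and scaled to the class's total UMIs, and ratios are log2 ratios of cKO over WT unless stated otherwise.

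The libraries differed in more than genotype and age. Xist, the RNA that coats the inactive X chromosome in females, was at 1220, 0.528, 1004 and 889 CPM in P10 WT, P10 cKO, P14 WT and P14 cKO. The Y-linked genes Uty and Ddx3y were at 106 and 59.9 CPM in P10 cKO, against 0.00693 and 0.0139 CPM in P10 WT, and Ddx3y was at 2.45 and 1.64 CPM in P14 WT and P14 cKO. Sex-linked RNA thus differed between the genotypes at P10 and between the ages in cKO. The count matrices were made with Cell Ranger 5.0.0 for P10 WT, 7.0.1 for P10 cKO and 7.1.0 for both P14 libraries, per the file headers. At P14 the genotypes shared a program version, so that comparison comes first.

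Over whole libraries Eftud2 RNA was slightly higher in cKO at P10 and slightly lower in cKO at P14. Eftud2 (ENSMUSG00000020929, chromosome 11, 102838473 to 102880985, minus strand, GRCm38) was at 52.1 CPM (50.9 to 53.3) in P10 WT and 55.7 (54.1 to 57.2) in P10 cKO, and at 47.3 (46.2 to 48.5) in P14 WT and 44.8 (43.4 to 46.3) in P14 cKO. In granule neurons, the small excitatory neurons that make up most of the cerebellum, it was at 41.1, 41.7, 34.9 and 38.6 CPM in P10 WT, P10 cKO, P14 WT and P14 cKO. With each cell thinned to 2000 UMIs, 7.38% (6.23 to 8.67), 8.41% (7.43 to 9.49), 6.73% (6.16 to 7.34) and 7.30% (6.35 to 8.34) of granule neurons had an Eftud2 UMI, and 75, 49, 58 and 52 shallower cells were left out. Without thinning the shares were 25.7%, 33.1%, 22.3% and 33.5%, at median depths of 6433, 9985, 7241 and 11836 UMIs. No class should lack this housekeeping gene, and its lowest level was in choroid plexus cells of P14 WT, at 12.1 CPM (8.18 to 17.3), with a UMI in 2.37% (1.09 to 4.45) of thinned cells and 6.82% of unthinned cells at a median of 5449 UMIs. At P14 the log2 ratio was 0.14 (0.04 to 0.25) in granule neurons, 0.39 (0.12 to 0.67) in GABAergic interneurons and 0.37 (0.06 to 0.66) in astroglia, and −0.46 (−0.66 to −0.26) in oligodendrocytes. A 3' tag outside the deleted part checks nothing, and the labels do not give the deleted part.

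No cluster of any library had the profile of Purkinje cells, so the class named in the title could not be compared. With 0 of 13723, 6417, 14876 and 6148 cells in such a cluster, the share of cells in such clusters is limited to 0.0219%, 0.0468%, 0.0202% and 0.0488% in P10 WT, P10 cKO, P14 WT and P14 cKO. This does not limit the share of Purkinje cells, since a few cells need not form a cluster. Cells with UMIs of at least 5 of 11 Purkinje markers numbered 3, 13, 5 and 5, or 0.0219% (0.00451 to 0.0639), 0.203% (0.108 to 0.346), 0.0336% (0.0109 to 0.0784) and 0.0813% (0.0264 to 0.190) of cells, under the 20 cells required. They were spread over 3, 5, 3 and 4 classes, with unnamed clusters taken as a class. These counts were not adjusted for depth, which differed between the libraries. Pcp2 (ENSMUSG00000004630, chromosome 8, 3623371 to 3625545), a gene expressed almost exclusively in Purkinje cells within the cerebellum, was at 1.96 CPM in P10 WT, 0.665 in P10 cKO, 0.639 in P14 WT and 1.41 in P14 cKO. Calb1, the calcium buffer calbindin, was at 1.09, 0.631, 1.499 and 0.979 CPM, and Car8, a carbonic anhydrase-like protein of Purkinje cells, at 6.84, 5.35, 7.01 and 6.005 CPM. Shh, the mitogen that Purkinje cells supply to granule cell progenitors, had 0 UMIs in the 10 classes compared. The protocol passed the suspension through a filter with a small pore size, per the labels, and Purkinje cells are large.

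Among the cells that were captured, GABAergic interneurons took a larger share in cKO at P14, at 2.88% (2.61 to 3.16) of WT and 9.37% (8.65 to 10.1) of cKO. Cells of that name made up 4.14% of P10 WT and 10.2% of P10 cKO, but those of P10 WT are uncertain as interneurons: interneuron markers summed to 713 CPM in them, against 2292, 2481 and 2351 CPM in P10 cKO, P14 WT and P14 cKO, and progenitor markers to 3361 CPM, against 652, 280 and 548 CPM. Granule cell progenitors, the dividing cells of the external granular layer, made up 25.8% and 22.1% at P10, and 15.9% (15.3 to 16.5) in P14 WT and 9.30% (8.59 to 10.1) in P14 cKO. Granule neurons made up 14.0% and 45.8% at P10, and 47.5% (46.7 to 48.3) and 45.2% (43.9 to 46.4) at P14. Astroglia made up 2.35% and 2.17% at P10, and 5.59% (5.22 to 5.97) and 3.46% (3.02 to 3.95) at P14. Microglia and border macrophages, the immune cells of the brain and of its coverings, differed in opposite directions at the 2 ages: microglia made up 8.53% and 2.77% at P10 and 4.35% and 6.41% at P14, and border macrophages 9.82% and 1.89% at P10 and 0.450% and 2.31% at P14. Oligodendrocytes made up 6.06% and 2.62% at P10, and 2.79% (2.53 to 3.07) and 11.5% (10.7 to 12.4) at P14; a cluster with a median of 1049 UMIs held 737, 27, 71 and 474 of these cells in P10 WT, P10 cKO, P14 WT and P14 cKO. Vessel and covering cells were more frequent in P10 WT than elsewhere: fibroblasts made up 9.20%, 1.84%, 1.98% and 2.02%, endothelial cells 6.14%, 1.32%, 1.82% and 1.38%, and blood leukocytes 1.30%, 0.312%, 0.686% and 0.488%. Choroid plexus cells, which secrete cerebrospinal fluid, made up 0.0947%, 0%, 2.86% and 0.228%, and 0 of 6417 cells in P10 cKO limits the share in such clusters to 0.0468%. Oligodendrocyte precursors (3.14%, 0.0623%, 0.0739% and 0.293%), mural cells (0.532%, 0.125%, 0.229% and 0.407%) and ependymal cells (0.291%, 0.0468%, 0.343% and 0.0325%) fell short of 20 cells in a library, and 8.61%, 8.76%, 12.6% and 7.58% of cells were in unnamed clusters. The largest cluster of granule neurons differed between the libraries (clusters 4, 1, 0 and 10), and interneurons of P10 WT were mostly in cluster 24 while those of the other libraries were in cluster 9. The largest clusters of P10 WT also differed from those of P10 cKO for progenitors (8 and 3), microglia (17 and 16), border macrophages (13 and 34), astroglia (20 and 22), oligodendrocytes (11 and 18) and leukocytes (41 and 38). A cluster mostly of 1 library may be that library and not a type. Shares depend on dissociation and dissection, and at doubled cluster resolution oligodendrocytes made up 0.605% of P14 WT and 8.47% of P14 cKO. At that resolution cells named oligodendrocyte precursors numbered at least 20 in each library, so the precursor shares above are also uncertain. Among cells with at least 1000 genes the P10 ratio of oligodendrocyte shares, cKO over WT, was 1.45 in place of 0.432. In that setting oligodendrocytes made up 5.13% of P14 cKO in place of 11.5%, while their share of P14 WT stayed within its counting interval. Small ratios turned with the settings: astroglia at P10 from 0.920 to 1.12 at no more than 10% mitochondrial UMIs, granule neurons at P14 from 0.951 to 1.01 among cells with at least 1000 genes, and, with each library clustered on its own, leukocytes at P14 from 0.712 to 1.53 and fibroblasts at P14 from 1.02 to 0.525.

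**Figure D1:**
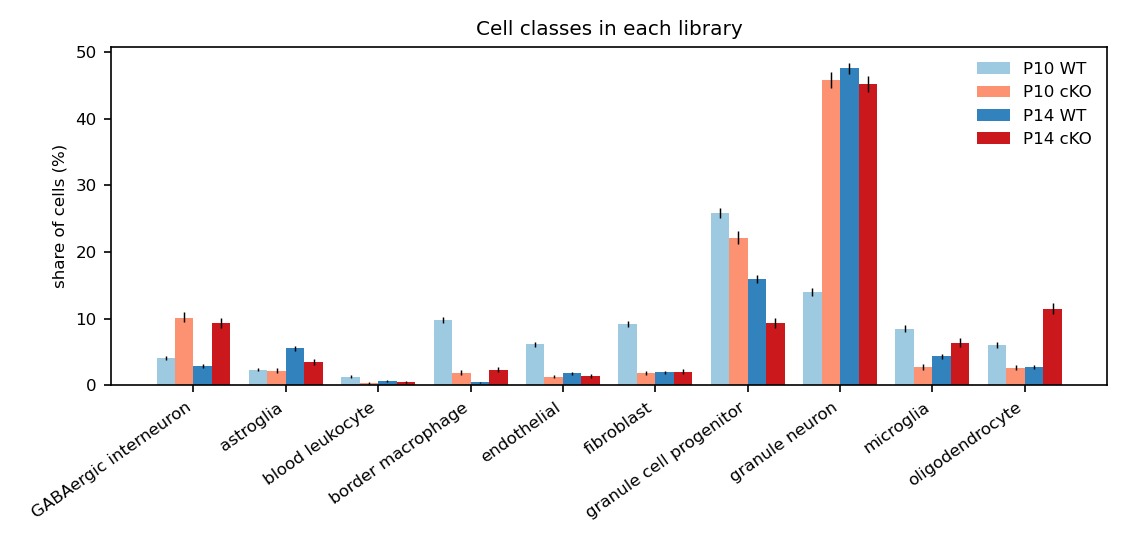
Share of cells (percent, bars from 0) in each cell class for P10 WT, P10 cKO, P14 WT and P14 cKO, with exact 95% binomial intervals for counting error as lines. GABAergic interneurons stand at 4.14% and 10.2% at P10 and at 2.88% and 9.37% at P14, WT before cKO.

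At P14, genes of the interferon response were higher in cKO in all 10 classes compared. These genes are switched on by type I interferons and restrict viruses. The list's median ratio was 1.997 (1.55 to 2.17) in astroglia with 15 of 15 members higher, 1.96 (1.44 to 2.63) in GABAergic interneurons with 10 of 11, 1.68 (1.42 to 2.05) in oligodendrocytes with 17 of 17 and 1.49 (1.33 to 1.64) in microglia with 17 of 18. It was 1.31 (0.87 to 1.63) in leukocytes, 1.12 (0.92 to 1.26) in fibroblasts, 1.03 (0.59 to 1.22) in granule cell progenitors, 0.97 (0.72 to 1.29) in granule neurons, 0.87 (0.76 to 1.19) in border macrophages and 0.80 (0.67 to 0.92) in endothelial cells. Each median lay above the range that holds 95% of 10000 random lists matched on expression.

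In microglia, Rsad2 (ENSMUSG00000020641, chromosome 12, 26442746 to 26456452), which encodes the antiviral enzyme viperin, was at 15.3 CPM in P14 WT and 136 CPM in P14 cKO, a ratio of 3.14 (2.82 to 3.49). Ifitm3, which blocks viral entry, was at 69.8 and 269 CPM (1.94, 1.78 to 2.11), and Irf7, the transcription factor that amplifies interferon production, at 18.0 and 63.3 CPM (1.81, 1.49 to 2.16). The exception among the 18 members was Ifi27, at 95.4 and 63.3 CPM (−0.59, −0.79 to −0.40). Bst2, which tethers budding virus to the cell surface, was at 227 and 496 CPM in microglia and at 8.70 and 51.2 CPM in astroglia (2.55, 2.15 to 2.98). In oligodendrocytes Ifit3, an RNA-binding antiviral protein, was at 1.44 and 38.3 CPM (4.68, 3.99 to 5.58), in fibroblasts Usp18, a negative regulator of the same pathway, at 11.7 and 56.1 CPM (2.25, 1.74 to 2.81), and in endothelial cells Isg15, a ubiquitin-like modifier, at 104 and 173 CPM (0.73, 0.50 to 0.96). Granule neurons held far less of this RNA: the list summed to 43.6 and 67.4 CPM there, against 1012 and 2715 CPM in microglia and 1541 and 2423 CPM in endothelial cells. Interneurons, at 38.2 and 94.2 CPM, and progenitors, at 67.0 and 81.4 CPM, also held little of it. RNA of microglia markers was also higher in cKO in classes that should lack it, at 38.7 and 86.1 CPM in granule neurons, 57.7 and 278 CPM in astroglia and 59.8 and 120 CPM in interneurons. With cells thinned to equal depth the median was 0.36 in granule cell progenitors and 1.10 in astroglia, and with clusters weighted alike in both libraries it was 0.53 in oligodendrocytes. One member in interneurons had 0 UMIs in WT, and with it set to a floor of 3 counts their median was 1.79.

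**Figure D2:**
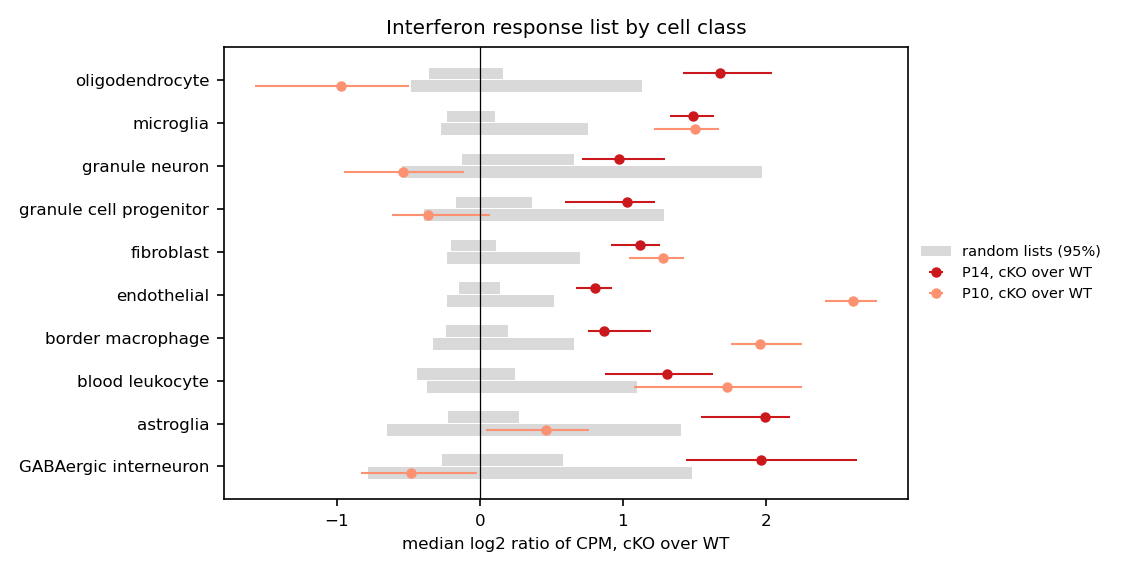
Median log2 ratio (cKO over WT) of the interferon response list in each cell class at P14 (dark red points) and P10 (light red points), with 95% counting intervals as lines and the range of 95% of random matched lists as grey bars. At P14 the medians run from 0.80 in endothelial cells to 1.997 in astroglia, and at P10 from −0.97 in oligodendrocytes to 2.61 in endothelial cells.

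Granule neurons of P14 cKO had more RNA of maturation genes and less of early genes than those of P14 WT. The median over 14 mature granule neuron genes was 2.08 (1.98 to 2.13), with 13 higher. Gabra6 (ENSMUSG00000020428, chromosome 11, 42306437 to 42321072), the GABA receptor subunit typical of mature granule neurons, was at 1.75 and 21.2 CPM, a ratio of 3.59 (3.29 to 3.92). Grin2c, the NMDA receptor subunit that replaces earlier subunits, was at 0.332 and 3.18 CPM (3.23, 2.53 to 4.07), Calb2, the calcium buffer calretinin, at 9.59 and 93.4 CPM (3.28, 3.15 to 3.42), and Kcnd2, an A-type potassium channel, at 263 and 1068 CPM (2.02, 1.99 to 2.05). Slc17a7, the vesicular glutamate transporter VGLUT1, was at 35.01 and 34.5 CPM (−0.02, −0.13 to 0.09). Early granule neuron genes had a median of −0.42 (−0.45 to −0.38), with 11 of 11 lower, among them Sox11, a transcription factor of immature neurons, at 1906 and 1391 CPM (−0.45, −0.47 to −0.44), and Nhlh1 at 206 and 143 CPM (−0.53, −0.58 to −0.48). Cluster 10, the largest granule neuron cluster of P14 cKO, held 0, 96, 255 and 1024 cells of P10 WT, P10 cKO, P14 WT and P14 cKO. Without that cluster the mature list's median was 1.79 and that of early genes −0.10, and with all granule neuron clusters weighted alike in both libraries the mature list stood at 0.13 (0.09 to 0.20) and the early list at −0.03. Among genes chosen by rank over both ages, Nebl, an actin-binding protein, was at 20.8 and 275 CPM (3.72, 3.63 to 3.81), and Grin2a, another NMDA receptor subunit, at 5.15 and 56.0 CPM (3.44, 3.26 to 3.63). Ranks over both ages, here and below, used P10 ratios that carry the difference by intron length described further down. For genes with long introns a higher ratio at P10 is therefore no second check. Mitochondrially encoded genes were at 0.25 in these cells, above the random range, and at 0.0038 with clusters weighted alike. Oligodendrocyte markers in the same cells summed to 134 and 473 CPM and choroid plexus markers to 211 and 30.0 CPM.

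Genes of the Shh response, the pathway through which Purkinje cells drive progenitor division, were lower in P14 cKO. Their median was −0.42 (−0.48 to −0.25) in granule neurons, with 7 of 10 lower, and −0.14 (−0.19 to −0.04) in granule cell progenitors, with 8 of 10 lower. The list was lower in 9 of 10 classes and below the random range in 6, so this was not particular to the granule lineage. Its medians ran from −1.57 to 0.32, with −0.91 in border macrophages and −0.61 in oligodendrocytes. In progenitors Ccnd1, which encodes the G1 cyclin D1, was at 114 and 72.1 CPM (−0.66, −0.76 to −0.55). Mycn, a mitogenic target, was at 52.9 and 54.0 CPM (0.03, −0.10 to 0.16). Cell cycle genes of progenitors had a median of −0.07 (−0.10 to −0.05), inside the range of random lists, with 18 of 22 lower. With clusters weighted alike the median was −0.12 (−0.15 to −0.09), below that range, and with thinned cells it was −0.14. In granule neurons the cell cycle list was at −0.28 (−0.43 to −0.20), or −0.07 (−0.13 to 0.08) with clusters weighted alike, and the Shh list was at −0.09 without cluster 10 and at −0.04 with clusters weighted alike.

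Astroglia of P14 cKO had higher reactive genes and lower Bergmann glia genes. Gfap (ENSMUSG00000020932, chromosome 11, 102887336 to 102900912), the intermediate filament raised in reactive astrocytes, was at 341 and 855 CPM (1.33, 1.25 to 1.41), and C4b, a complement component, at 7.098 and 31.6 CPM (2.15, 1.67 to 2.65). The reactive list's median was 1.01 (0.51 to 1.21), with 13 of 15 higher, and H2-D1, a class I histocompatibility gene that also answers to interferon, was at 29.9 and 72.5 CPM (1.28, 1.01 to 1.55). Bergmann glia, the radial astroglia that wrap Purkinje cell dendrites, express Gdf10, which was at 777 and 409 CPM (−0.92, −1.02 to −0.83), Slc1a3, the glutamate transporter GLAST, at 5216 and 2800 CPM (−0.90, −0.93 to −0.86), and Sept4 at 881 and 439 CPM (−1.004, −1.09 to −0.92). That list's median was −0.55 (−0.61 to −0.49), with 9 of 12 lower. Cholesterol synthesis genes were at −0.39 (−0.45 to −0.26), with 18 of 18 lower. Among them Cyp51, a sterol demethylase, was at 285 and 181 CPM (−0.65, −0.79 to −0.51), and Sqle, squalene epoxidase, at 118 and 86.4 CPM (−0.44, −0.65 to −0.24). This was not particular to astroglia: the list was lower in 9 of 10 classes and below the random range in 4. It was at −0.94 in border macrophages and −0.73 in fibroblasts. Genes higher at both ages, with the intron length trend left in at P10, were led by Camk1d, a calcium-dependent kinase, at 246 and 696 CPM at P14 (1.502, 1.41 to 1.59). Astroglia came mainly from cluster 22 in P14 WT and from cluster 27 in P14 cKO. With clusters weighted alike the reactive list was at 0.81 and the Bergmann glia list at −0.27. As means of per-cell CPM they were at 0.50 and −0.45, and with members of at least 5 UMIs the reactive list was at 1.30. The summed astroglia markers were at 24533 and 24180 CPM, and RNA of oligodendrocyte markers in astroglia was at 481 and 878 CPM. Mitochondrially encoded genes, which mark RNA quality, were at 0.38 in these cells, or −0.17 with clusters weighted alike.

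Microglia of P14 cKO had higher interferon genes and higher genes of disease-associated microglia, and lower levels of single homeostatic genes. Tmem119 (ENSMUSG00000054675, chromosome 5, 113793729 to 113800516), a surface protein of resting microglia, was at 440 and 214 CPM (−1.04, −1.14 to −0.94), and P2ry12, the purinergic receptor that guides microglial processes, at 1245 and 855 CPM (−0.54, −0.59 to −0.49). The homeostatic list was at −0.18 (−0.26 to −0.16), with 11 of 12 lower, inside the range of random lists at percentile 15.6. Genes of disease-associated microglia were at 0.39 (0.35 to 0.47), with 21 of 22 higher, among them Lgals3, the lectin galectin-3, at 28.0 and 67.0 CPM (1.26, 0.98 to 1.54), and Axl, a receptor for apoptotic cells, at 64.1 and 111 CPM (0.79, 0.60 to 0.98); Spp1, osteopontin, was at 92.5 and 78.9 CPM (−0.23, −0.41 to −0.04). That list was not particular to microglia: it was higher in 9 of 10 classes and above the random range in 5, with medians of 0.83 in interneurons, 0.43 in astroglia (0.16 with clusters weighted alike) and 0.42 in granule neurons. Immediate early and dissociation genes were lower, at −0.44 (−0.49 to −0.41) with 18 of 19 lower, and Socs3, a feedback inhibitor of cytokine signalling, was at 129 and 62.6 CPM (−1.05, −1.23 to −0.86). Among the genes that ranked highest over both ages, Ifi204, at 27.1 and 161 CPM (2.57, 2.32 to 2.84), belongs to a family of near-identical neighbours, so its count is uncertain, and Rtp4, an interferon-induced gene, was at 35.4 and 128 CPM (1.85, 1.62 to 2.09). Ctse, the protease cathepsin E, was among the lowest at both ages, at 47.9 and 4.70 CPM (−3.32, −3.97 to −2.78). Oligodendrocyte markers in microglia summed to 126 and 615 CPM.

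Cells named oligodendrocytes had higher myelin genes and lower cell cycle genes in P14 cKO, but the class may also hold precursors. The median over 12 myelin genes was 0.98 (0.96 to 0.99), with 12 of 12 higher, and Opalin (ENSMUSG00000050121, chromosome 19, 41061710 to 41077113), a membrane protein of myelinating cells, was at 81.0 and 387 CPM (2.26, 2.15 to 2.36). Mobp, a myelin structural protein, was at 1686 and 4143 CPM (1.30, 1.27 to 1.32), and Mbp at 6170 and 8102 CPM (0.39, 0.38 to 0.41). Cell cycle genes were at −1.08 (−1.19 to −0.84), with 22 of 22 lower, and Top2a, the mitotic topoisomerase, was at 32.6 and 10.4 CPM (−1.64, −1.94 to −1.35). Cholesterol synthesis genes were at 0.26 (0.21 to 0.31), with 16 of 18 higher; Hmgcs1 was at 950 and 1608 CPM (0.76, 0.72 to 0.79). Scd1, a fatty acid desaturase, was at 11.4 and 21.8 CPM (0.94, 0.63 to 1.26), and Cdh19, a cadherin, was higher at both ages, at 45.2 and 205 CPM at P14 (2.18, 2.04 to 2.32). These cells came mainly from cluster 18 in P14 WT and from the low-UMI cluster 11 in P14 cKO. Oligodendrocyte precursor markers in them summed to 2619 CPM in P14 WT and 2080 CPM in P14 cKO. A different mix of precursors and mature cells was not told apart from a change in oligodendrocytes. At doubled cluster resolution the myelin median was 0.18 and the cholesterol median −0.20, and with each library clustered on its own they were 0.08 and 0.03.

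Cell cycle genes were higher in GABAergic interneurons of P14 cKO, but this depended on how the cells were clustered. The median was 1.36 (1.14 to 1.84), with 21 of 22 higher, and Top2a was at 9.46 and 70.3 CPM (2.87, 2.34 to 3.50), but the median was −0.01 at doubled cluster resolution, 0.43 with called doublets kept and 0.83 with each library clustered on its own. Dgkb, a diacylglycerol kinase, was higher at both ages with the intron length trend left in at P10, and was at 10.8 and 48.6 CPM at P14 (2.15, 1.65 to 2.74). Plcl1, a phospholipase C-like protein, was at 251 and 88.6 CPM (−1.501, −1.66 to −1.35). Markers of granule cell progenitors in interneurons summed to 280 and 548 CPM.

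Lists tied to splicing and cell stress had medians between −0.37 and 0.35 at P14. The U5 and tri-snRNP spliceosome list ran from −0.25 in fibroblasts to 0.07 in interneurons, lower in 9 of 10 classes and below the random range in 2, and was at −0.10 (−0.13 to −0.05) in granule neurons with 5 of 20 higher. Targets of p53, the DNA damage factor, ran from −0.37 in oligodendrocytes to 0.07, with 2 classes below the random range and 0 above, and were at −0.17 (−0.22 to −0.10) in granule neurons, or 0.02 without cluster 10. With clusters weighted alike they were at 0.11 in oligodendrocytes and −0.011 in granule neurons. In granule neurons Trp53 was at 55.9 and 40.7 CPM (−0.46, −0.55 to −0.36) and Cdkn1a, the p21 cell cycle inhibitor, at 7.80 and 13.7 CPM (0.82, 0.62 to 1.01). ATF4 and integrated stress response targets ran from −0.25 to 0.23, above the random range in astroglia (0.23) and interneurons (0.19) and below it in microglia (−0.22), where Atf4 itself was at 250 and 143 CPM (−0.81, −0.93 to −0.68). With clusters weighted alike the ATF4 list was at 0.08 in astroglia and 0.17 in interneurons, inside the random range, and at −0.21 in microglia, below it. Ferroptosis and iron handling genes ran from −0.12 to 0.21, the latter in astroglia, where they were at 0.04 with clusters weighted alike. Hypoxia response genes ran from −0.29 to 0.35, and fatty acid desaturation and tetrahydrobiopterin genes from −0.27 to 0.30, above the random range in 3 classes, with the highest median in microglia. There Scd2 was at 69.6 and 117 CPM (0.75, 0.57 to 0.94) and Gch1, which makes tetrahydrobiopterin, at 43.7 and 53.9 CPM (0.30, 0.05 to 0.55). Purkinje synapse and calcium signalling genes ran from −0.99 to 0.48, highest in granule neurons, where 21 of 29 were higher and the median was 0.11 (0.06 to 0.15) with clusters weighted alike. The zebrin II type list ran from −0.42 in oligodendrocytes (0.29 with clusters weighted alike) to 0.31, the zebrin II negative type list from −0.42 to 0.15 and Purkinje secreted signals from −0.07 to 0.81, none of them measured in Purkinje cells. Mitochondrially encoded genes ran from −0.19 in interneurons to 0.38 in astroglia, where they were at −0.17 (−0.22 to −0.14) with clusters weighted alike. Sex-linked genes ran from −0.40 to −0.14 in 4 classes.

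RNA of other cell types differed between the P14 libraries in every class, so small shared differences are not particular to a class. Myelin genes were higher in cKO in 10 of 10 classes, with medians from 0.98 in oligodendrocytes to 2.504 in microglia, and 2.37 in granule neurons. Bergmann glia genes were lower in 10 of 10, from −1.04 to −0.25, and homeostatic microglia genes were higher in astroglia (1.23) and granule neurons (0.94). Ttr (chromosome 18, 20665280 to 20674321), the transthyretin of the choroid plexus, was at 5688 CPM in the whole P14 WT library and at 167 CPM in P14 cKO, and at 192 and 6.15 CPM in granule neurons. Haemoglobin genes ran from −4.23 in fibroblasts to 2.84 in granule cell progenitors, and with clusters weighted alike in both libraries these medians were 0.65 (0.21 to 1.14) and 0.87.

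At P10 the interferon response was higher in cKO in immune and vessel cells, and not in neurons. Of the 10 classes compared, only endothelial cells and fibroblasts had the same largest cluster in P10 WT and P10 cKO. In granule neurons these were 4 and 1, and in interneurons 24 and 9. The list's median was 2.61 (2.42 to 2.78) in endothelial cells with 17 of 18 members higher, 1.96 (1.75 to 2.25) in border macrophages with 17 of 17, 1.72 (1.08 to 2.25) in leukocytes with 9 of 10, 1.51 (1.22 to 1.67) in microglia with 15 of 16 and 1.28 (1.04 to 1.43) in fibroblasts with 14 of 17. It was −0.54 (−0.95 to −0.11) in granule neurons, −0.36 (−0.62 to 0.07) in progenitors, −0.48 (−0.84 to −0.02) in interneurons and 0.46 (0.04 to 0.76) in astroglia, inside the range of random lists, and −0.97 (−1.57 to −0.50) in oligodendrocytes, below it. With thinned cells the granule neuron median was 0.49, and at doubled cluster resolution the oligodendrocyte median was 0.09. In endothelial cells Isg15 was at 15.1 and 181 CPM (3.59, 3.30 to 3.88). In microglia Bst2 was at 108 and 221 CPM (1.03, 0.86 to 1.20), while Rsad2 was at 2.41 and 1.59 CPM (−0.41, −2.99 to 1.15).

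The P10 libraries also differed by intron length, which none of these values take out. Genes in the longest of 20 bins of intron length, from 152 kb, had higher ratios than genes in the shortest bin, up to 400 bp, by 2.20 to 3.11 over the 10 classes at P10, and by −0.49 to 0.24 at P14. The longest bin took 4.02% of UMIs in P10 WT and 20.8%, 18.6% and 20.5% in P10 cKO, P14 WT and P14 cKO. With the trend removed the interferon medians stood at 2.58 in endothelial cells, 1.96 in border macrophages and 1.64 in microglia. Scaling by TMM factors in place of total UMIs moved the P10 medians by 0.48 in leukocytes, 0.30 in fibroblasts, 0.25 in microglia and 0.13 to 0.22 in 4 other classes. Dcc, an axon guidance receptor with long introns, was at 188 and 3851 CPM in granule neurons (4.36, 4.30 to 4.41), and at 2.03 with the trend removed.

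**Figure D3:**
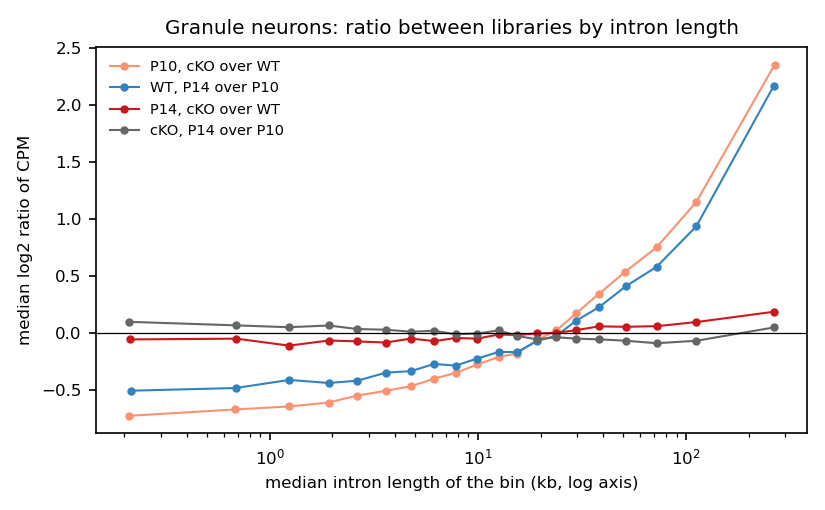
Median log2 ratio of genes in bins of intron length in granule neurons (horizontal axis, median intron length of the bin, log scale) for P10 cKO over WT, P14 cKO over WT, WT P14 over P10 and cKO P14 over P10. The longest bin exceeds the shortest by 3.08 at P10 and 2.67 in WT across ages, against 0.24 at P14 and −0.05 in cKO across ages.

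In granule neurons at P10 the mature list was at 1.96 (1.72 to 2.02) with 12 of 14 higher, and at 0.57 with the intron trend removed; Gabra6 was at 0.681 and 5.01 CPM (2.81, 1.96 to 3.97). Early genes were at −0.44 (−0.49 to −0.42), and at −0.02 with the trend removed. Shh response genes of progenitors were at 0.51 (0.25 to 0.79), within the random range, and at 0.35 with the trend removed, above it. Cell cycle genes were lower in oligodendrocytes, at −2.80, and in interneurons, at −2.34 (0.16 with each library clustered on its own), where Top2a was at 443 and 83.1 CPM (−2.41, −2.54 to −2.29) and interneuron markers summed to 713 and 2292 CPM, so the name is uncertain for the P10 WT cells. Myelin genes were lower in 10 of 10 classes, from −1.16 in astroglia to −0.45 in endothelial cells, and were at −0.56 in oligodendrocytes, or 0.85 as a mean of per-cell CPM. Disease-associated microglia genes ran from −4.14 in oligodendrocytes (−3.39 with members at 0 set to a floor of 3 counts) to −0.26 in microglia, and homeostatic microglia genes from −2.23 to −0.37. In microglia Tmem119 was at 356 and 243 CPM (−0.55, −0.70 to −0.41) and Lgals3 at 40.2 and 7.96 CPM (−2.29, −3.19 to −1.59). Reactive genes of astroglia were at −0.33 (−0.80 to −0.12), or −0.03 with the trend removed, and Gfap was at 1371 and 756 CPM (−0.86, −0.95 to −0.77). Bergmann glia genes were at 0.39 (0.14 to 0.58) there, or 0.08 with thinned cells and 0.12 as a mean of per-cell CPM. Cholesterol synthesis genes of astroglia were at −0.14 (−0.22 to −0.02), or 0.05 with the trend removed. The U5 and tri-snRNP list ran from −0.53 in interneurons to −0.01 in leukocytes, p53 targets from −0.42 to 0.16, ATF4 targets from −0.80 to 0.01, ferroptosis genes from −0.82 to −0.19 and immediate early genes from −2.54 to −0.29. With the trend removed these ran from −0.40 to 0.07, −0.12 to 0.33, −0.39 to 0.03, −0.47 to −0.12 and −2.10 to −0.12, and the classes below the random range numbered 2, 0, 3, 4 and 4 in place of 3, 2, 7, 6 and 9. Sex-linked genes, of which the 4 Y-linked ones were higher and 2 others lower in each of 9 classes, had medians of 5.02 in astroglia to 9.42 in granule cell progenitors with members at 0 set to the floor. Haemoglobin genes, a sign of blood in the suspension, were lower in cKO in 10 of 10 classes, from −8.61 to −1.59, and erythroid markers in granule neurons summed to 6037 CPM in P10 WT and 194 CPM in P10 cKO.

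With both ages fitted together, edgeR called no gene changed by genotype in any class, while other settings called some. The edgeR quasi-likelihood test, with age as a term and 1 residual degree of freedom, had 0 genes at an adjusted p of 0.05 in each of the 10 classes, among 7971 to 15902 genes tested. At an unadjusted p under 0.05 it had 470 of 12377 genes in fibroblasts, 413 of 15902 in granule neurons and 307 of 11217 in endothelial cells. It had 222 of 12334 in microglia, 196 of 9535 in border macrophages, 147 of 13481 in oligodendrocytes and 112 of 7971 in leukocytes. The rest were 104 of 13356 in interneurons, 66 of 12238 in astroglia and 56 of 15534 in progenitors. In every class this was under the share of 0.05 that would pass by chance if no gene changed. The smallest adjusted p of this test was 0.208, in fibroblasts. DESeq2's Wald test called 107 genes in granule neurons (106 higher, 1 lower), 6 each in border macrophages, endothelial cells and oligodendrocytes, 5 in fibroblasts, 2 each in astroglia and progenitors, 1 each in interneurons and microglia, and 0 in leukocytes. Without the low-count filter edgeR called 100 genes in microglia, 67 in border macrophages, 34 in endothelial cells, 18 in leukocytes, 8 in fibroblasts, 3 each in interneurons, astroglia and progenitors, and 0 in granule neurons and oligodendrocytes. On data simulated at the dispersions fitted in these classes, 0.103 to 0.263, edgeR recovered 0% to 45% of 4-fold changes and 0% to 1% of 2-fold changes, so 0 calls do not show that genes were unchanged. The fit takes 1 genotype effect for both ages and holds the difference of program versions at P10.

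From P10 to P14 in cKO, granule neurons shifted their levels toward maturity and several classes had higher interferon genes. The largest clusters of the 2 cKO libraries differed for granule neurons (1 and 10) and oligodendrocytes (18 and the low-UMI cluster 11). Astroglia came mainly from clusters 22 and 27 at P10 and from 27 and 20 at P14. Cluster makeup was not evened out across ages, so ratios in these classes may reflect it. In granule neurons the mature list's ratio of P14 over P10 was 0.85 (0.77 to 0.95), with 14 of 14 higher, the cell cycle list was at −0.98 (−1.10 to −0.82), with 21 of 22 lower, and the Shh response at −0.67 (−0.77 to −0.55). Gabra6 was higher by 2.08 (1.83 to 2.33) and Nebl by 4.11 (3.99 to 4.24). In progenitors 10 of 10 Shh response genes were lower, with a median of −0.70 (−0.75 to −0.62). Boc, a Shh co-receptor, was at −1.15 (−1.24 to −1.05) and Ccnd1 at −0.70 (−0.81 to −0.59). The Shh response list was lower in 8 of 9 classes and below the random range in 7. Of the cell cycle genes in progenitors, 21 of 22 were higher, with a median of 0.15 (0.13 to 0.20). The interferon list was above the random range in 8 of 10 classes, at 3.43 in oligodendrocytes, 2.34 in astroglia (1.94 with a member at 0 set to the floor), 1.55 in microglia and 1.39 in granule neurons, and was at −0.04 (−0.19 to 0.07) in endothelial cells. Astroglia had 18 of 18 cholesterol synthesis genes lower, at −0.83 (−0.92 to −0.72), and Bergmann glia genes at −0.35 (−0.44 to −0.31). Immediate early and dissociation genes, which rise when tissue is taken apart, were above the random range in 8 of 10 classes, at 1.52 in endothelial cells, 0.89 in astroglia and 0.74 in progenitors. Disease-associated microglia genes were above it in 10 of 10 classes, or in 8 with the intron trend removed. They were at 0.52 (0.45 to 0.57) in microglia and 1.01 in oligodendrocytes. Homeostatic genes of microglia were at −0.12 (−0.17 to −0.05), or 0.11 with TMM factors. Myelin genes were at 0.17 (0.16 to 0.19) in oligodendrocytes and higher in 10 of 10 classes. Of 6 sex-linked genes, 4 were lower and 2 higher in each of 9 classes. Xist went from 0.528 to 889 CPM over the whole libraries, so these ratios also compare animals of different sex. The list's medians, which the 4 Y-linked genes set, were −6.70 in granule neurons to −4.18 in border macrophages once members at 0 were set to the floor.

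From P10 to P14 in WT the ratios carried the intron length trend, by 2.20 to 3.06 between the outer bins. Of the 10 classes compared, all but endothelial cells and fibroblasts also had different largest clusters in these libraries, among them microglia (17 and 16), astroglia (20 and 22), oligodendrocytes (11 and 18) and granule neurons (4 and 0). Interferon genes of microglia were higher at P14, by 2.46 (2.11 to 2.74), or 2.42 with the trend removed, and they were at 0.20 (−0.40 to 0.37) in granule neurons. The mature granule neuron list was at 1.29 (0.89 to 1.72) and at 0.41 with the trend removed, the early list at −0.38 and −0.17, and the cell cycle list of granule neurons at −0.996 (−1.11 to −0.87) and −0.80. Bergmann glia genes of astroglia were at 0.82 (0.69 to 0.88) and 0.66, with 9 of 12 higher. Myelin genes of oligodendrocytes were at −1.31 (−1.33 to −1.29) and −1.51. In microglia, disease-associated genes were at −0.27 (−0.29 to −0.22), or 0.04 with the trend removed, and homeostatic genes at −0.29 and −0.05. Haemoglobin genes ran from −10.66 to −0.997.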

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

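Tests of cluster makeup within microglia and within 6 other classes, of libraries per group and of intron length were chosen after the results had been seen. In 18 cases a list's median ratio (log2, cKO over WT) had opposite signs at P14 and P10, by limits chosen after the values were seen. The size was at least 0.5 at both ages, and at P10 also with the intron trend removed. The P14 median and the trend-removed P10 median lay outside the random range, and the list had at least 5 members at each age. This left out haemoglobin genes, with 4 members at P14, which were lower in 10 of 10 classes at P10 and higher in 8 of 9 at P14. The differences were not tested.

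In GABAergic interneurons, a name that is uncertain for the cells of P10 WT, the medians at P14 and P10 were 1.36 and −2.34 for cell cycle genes, 0.83 and −1.22 for disease-associated microglia genes, 0.69 and −0.96 for homeostatic microglia genes, 0.56 and −1.25 for reactive astroglia genes and 1.26 and −0.59 for myelin genes. In astroglia they were 1.23 and −1.09 for homeostatic microglia genes and 2.02 and −1.16 for myelin genes. Granule neurons had 0.94 and −1.68 for homeostatic microglia genes and 2.37 and −0.69 for myelin genes, and granule cell progenitors 0.57 and −1.68, and 2.11 and −1.02. Myelin genes were at 2.504 and −1.01 in microglia, 1.93 and −0.91 in border macrophages, 1.89 and −0.71 in fibroblasts and 0.98 and −0.56 in oligodendrocytes. Interferon response genes of oligodendrocytes were at 1.68 and −0.97, cell cycle genes of leukocytes at −0.89 and 0.61, and early granule neuron genes of fibroblasts at −0.57 and 0.67. Some of these did not hold in other settings: at doubled cluster resolution oligodendrocyte interferon genes were at 0.085 at P10 and interneuron cell cycle genes at −0.010 at P14, with each library clustered on its own interneuron cell cycle genes were at 0.16 at P10, and as a mean of per-cell CPM oligodendrocyte myelin genes were at 0.85 at P10.

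The interferon response list was higher in P14 cKO in 10 of 10 classes, which could come from RNA of other cells, from cluster makeup, from the animal, or from genotype. RNA of other cells is an unlikely source in microglia and endothelial cells. Their rise in summed CPM was at least 37.1 times that in granule neurons. In granule neurons such RNA could account for 34.5 CPM, or 51.2% of the list's 67.4 CPM in P14 cKO. This exceeds the whole rise of 23.8 CPM from P14 WT, but the estimate was not made in P14 WT. How much of the rise it gives therefore stays open. That last estimate was widened after it was seen, from 4 source classes (23.2%, which met the bound written for the other outcome) to 8, because the first set left out border macrophages and other sources. Outside microglia, endothelial cells and granule neurons this source was not tested, and it stays open there. Interneurons and progenitors held as little of the list's RNA as granule neurons. With equal cluster weights the median lay above the random range in 9 of 9 classes, so the bound written beforehand, at least 8, was met. A median alone takes no account of counting error, so the counting interval was brought in after the values were seen. The whole interval lay above the range in 7 classes (microglia stood at 1.46, and the narrowest gap of the other 6 was 0.048), where makeup across these clusters is an unlikely source. In border macrophages, endothelial cells and fibroblasts only 1 cluster entered, so nothing was reweighted there. A different mix within a cluster was not tested. Interneuron cell cycle genes, for example, were at 1.24 (0.91 to 1.63) with equal weights but at −0.01 at doubled cluster resolution. Makeup across clusters stays open in progenitors, at 0.80 (0.29 to 0.98) against random lists up to 0.37, and in oligodendrocytes, at 0.53 (0.35 to 1.11) against 0.40. Leukocytes were not tested. With 1 library per group, an infection or another difference between animals might give the same pattern, and this remains open.

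The mature granule neuron list was higher in granule neurons of P14 cKO, which could come from depth per cell, from cluster makeup or from faster maturation in the cKO animal. Depth is an unlikely source, since the median was 2.20 with thinned cells. With equal cluster weights it was 0.13 (0.09 to 0.20), against random lists from −0.09 to 0.11; the bound written beforehand took the median alone, which lies above that range, and the counting interval was brought in after the values were seen. The clusters were made with these genes, so the value places the difference between clusters and may not tell a different mix of cells from a change of state.

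Genes with long introns were higher in P10 cKO than in P10 WT, which could come from introns being counted in 1 library or from loss of a spliceosome protein. Between P14 WT and P10 WT, where genotype does not differ, the outer bins of intron length differed by at least 2.20 in every class, a pattern that counted introns would give. Between genotypes at P14 they differed by at most 0.49, short of the bound set for spliceosome loss. The title names Purkinje cells as the deficient cells and no class compared holds them, so this could not test such loss. The intron setting itself is not stated, and age also differs between the WT libraries. Between the cKO libraries of the same ages the outer bins differed by −0.46 to 0.21 over the classes.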

How the results depend on the processing

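The trend removal, the equal cluster makeup and the runs without cluster 10 or 11 were chosen after the data were seen. Of 1181 values recomputed under an alternative setting, 861 stayed within their counting spread, or within 1.5 times for counts of genes. Another 301 moved by more and 19 were marked as turned in direction, and the cause was not tested. A median was marked as turned only where its counting interval left out 0. Some medians near 0 thus changed sign among the 861 and the 301, such as ferroptosis genes in P14 granule neurons, from 0.017 to −0.069 with thinned cells. The interferon medians at P14 kept their direction in each class under each setting that gave a value there; equal cluster makeup gave none in leukocytes. Purkinje-like comparisons were not run, for want of cells, and leaving out a library gives no test, for want of residual degrees of freedom. No paired analysis was possible because the labels carry no replicate numbers and each group has 1 library. Depth limits genes with few UMIs, most of all in leukocytes, with 20 cells in P10 cKO. Of the values that moved, 83 for results of lesser weight (share ratios, shares of unnamed cells and of classes not compared, and Eftud2 shares outside granule neurons) are left out. The others that moved, and all marked as turned, follow by setting, with medians as log2 ratios of cKO over WT unless ages are named.

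With Purkinje-like cells taken by at least 5 of 11 markers, Purkinje-like shares (%) were: P10 cKO 0.203, P14 WT 0.0336, P14 cKO 0.0813. At 1000 genes or more per cell, shares (%) were: interneuron P14 cKO 10.2, leukocyte P10 WT 1.04, border macrophage P10 WT 9.23, endothelial P14 WT 1.60, fibroblast P10 WT 9.88, progenitor P10 WT 29.2 and P14 WT 16.7 and P14 cKO 10.5, granule neuron P10 WT 15.5 and P14 WT 49.97 and P14 cKO 50.3, microglia P14 WT 3.95, oligodendrocyte P10 WT 1.68 and P14 cKO 5.13. At 1000 genes or more per cell, cKO over WT share ratios were: granule neuron P14 1.01, oligodendrocyte P10 1.45. At 1000 genes or more per cell, P14 medians were: myelin oligodendrocyte 1.00. At 1000 genes or more per cell, P10 medians were: myelin oligodendrocyte −0.81, cholesterol synthesis oligodendrocyte −0.52. At 10% mitochondrial UMIs or less, shares (%) were: astroglia P10 WT 1.77 and P14 WT 5.08, progenitor P10 WT 26.6, granule neuron P14 WT 48.4, oligodendrocyte P10 WT 5.31. At 10% mitochondrial UMIs or less, cKO over WT share ratios were: astroglia P10 1.12. At 10% mitochondrial UMIs or less, P10 medians were: cholesterol synthesis astroglia −0.25, myelin oligodendrocyte −0.60. With called doublets kept, shares (%) were: progenitor P10 WT 24.9, granule neuron P14 WT 46.3. With called doublets kept, P14 medians were: interferon border macrophage 0.70, cell cycle interneuron 0.43. With called doublets kept, P10 medians were: cell cycle interneuron −1.80. With each library clustered on its own, shares (%) were: interneuron P10 WT 3.38, leukocyte P10 cKO 0 and P14 WT 1.02 and P14 cKO 1.56, endothelial P10 WT 5.41 and P14 WT 2.12, fibroblast P14 WT 3.04 and P14 cKO 1.59, progenitor P10 WT 24.9 and P10 cKO 24.7 and P14 WT 16.8, granule neuron P10 WT 13.3 and P10 cKO 36.2 and P14 cKO 42.0, microglia P10 WT 9.33 and P10 cKO 3.66, oligodendrocyte P10 WT 4.18 and P10 cKO 0.655 and P14 WT 0.847 and P14 cKO 5.03. With each library clustered on its own, cKO over WT share ratios were: leukocyte P14 1.53, fibroblast P14 0.525. With each library clustered on its own, P10 medians were: interferon astroglia 1.15 and microglia 2.28 and oligodendrocyte −0.38, mature granule neuron granule neuron 2.37, early granule neuron granule neuron −0.54, cell cycle progenitor −0.56 and interneuron 0.16, cholesterol synthesis astroglia −0.23 and oligodendrocyte 0.018, homeostatic microglia microglia −0.54, myelin oligodendrocyte −0.044, U5 and tri-snRNP interneuron −0.45 and granule neuron −0.52, ferroptosis and iron handling granule neuron −0.69. With each library clustered on its own, P14 medians were: interferon progenitor 1.34 and oligodendrocyte 1.18, mature granule neuron granule neuron 1.92, early granule neuron granule neuron −0.37, cell cycle progenitor −0.039 and interneuron 0.83, homeostatic microglia microglia −0.16, myelin oligodendrocyte 0.085, cholesterol synthesis oligodendrocyte 0.028. At doubled Leiden resolution, shares (%) were: interneuron P10 WT 3.34 and P10 cKO 8.88, fibroblast P10 WT 10.2, progenitor P10 cKO 23.7 and P14 WT 16.7, granule neuron P10 cKO 43.8 and P14 WT 46.4 and P14 cKO 40.4, oligodendrocyte P10 WT 1.76 and P10 cKO 1.25 and P14 WT 0.605 and P14 cKO 8.47. At doubled Leiden resolution, P14 medians were: interferon granule neuron 0.66, early granule neuron granule neuron −0.37, homeostatic microglia microglia −0.16, myelin oligodendrocyte 0.18, cholesterol synthesis oligodendrocyte −0.20, cell cycle interneuron −0.010. At doubled Leiden resolution, P10 medians were: interferon oligodendrocyte 0.085, cell cycle progenitor −0.50 and interneuron −1.60, myelin oligodendrocyte −0.23, cholesterol synthesis oligodendrocyte −0.21. Under the DESeq2 Wald test, genes called numbered: interneuron 1, astroglia 2, border macrophage 6, endothelial 6, fibroblast 5, progenitor 2, granule neuron 107, microglia 1, oligodendrocyte 6. With DESeq2 size factors in edgeR, genes called numbered: fibroblast 1. Without a low-count filter, genes called numbered: interneuron 3, astroglia 3, leukocyte 18, border macrophage 67, endothelial 34, fibroblast 8, progenitor 3, microglia 100. With TMM factors, P10 medians were: interferon border macrophage 1.74 and endothelial 2.39 and fibroblast 0.98, early granule neuron granule neuron −0.42, cell cycle progenitor −0.67, cholesterol synthesis astroglia −0.24 and oligodendrocyte −0.45, disease-associated microglia microglia −0.51, homeostatic microglia microglia −0.62, myelin oligodendrocyte −0.69. With TMM factors, P14 medians were: early granule neuron granule neuron −0.48, homeostatic microglia microglia −0.14, myelin oligodendrocyte 1.05, cholesterol synthesis oligodendrocyte 0.33, U5 and tri-snRNP granule neuron −0.15, p53 targets granule neuron −0.23, ATF4 and integrated stress response targets granule neuron −0.041. With TMM factors, WT P14 over P10 medians were: early granule neuron granule neuron −0.32, cell cycle progenitor −0.28, myelin oligodendrocyte −1.37, disease-associated microglia microglia −0.32, homeostatic microglia microglia −0.35. With TMM factors, cKO P14 over P10 medians were: myelin oligodendrocyte 0.27, disease-associated microglia microglia 0.75, homeostatic microglia microglia 0.11. As a mean of per-cell CPM, P14 medians were: interferon border macrophage 0.57, mature granule neuron granule neuron 2.21, early granule neuron granule neuron −0.50, reactive astroglia astroglia 0.50, Bergmann glia astroglia −0.45, myelin oligodendrocyte 0.76, cholesterol synthesis oligodendrocyte 0.11, cell cycle interneuron 0.84, ferroptosis and iron handling granule neuron −0.058. As a mean of per-cell CPM, P10 medians were: interferon endothelial 2.32 and fibroblast 1.52, cell cycle progenitor −0.55 and interneuron −2.13, Bergmann glia astroglia 0.12, cholesterol synthesis astroglia 0.011 and oligodendrocyte 0.79, myelin oligodendrocyte 0.85, U5 and tri-snRNP interneuron −0.63. With cells thinned to 2000 UMIs, P14 medians were: interferon astroglia 1.10 and endothelial 1.00 and fibroblast 0.70 and progenitor 0.36 and oligodendrocyte 2.23, mature granule neuron granule neuron 2.20, early granule neuron granule neuron −0.48, cell cycle progenitor −0.14, homeostatic microglia microglia −0.31, myelin oligodendrocyte 1.24, ferroptosis and iron handling granule neuron −0.069. With cells thinned to 2000 UMIs, P10 medians were: interferon endothelial 2.13 and fibroblast 1.52 and granule neuron 0.49, early granule neuron granule neuron −0.50, Bergmann glia astroglia 0.078, homeostatic microglia microglia −0.41, myelin oligodendrocyte −0.22, cholesterol synthesis oligodendrocyte 0.30, U5 and tri-snRNP interneuron −0.68, ATF4 and integrated stress response targets granule neuron −0.22. With the granule neuron profile subtracted, P10 medians were: cell cycle progenitor −0.54 and interneuron −2.69, myelin oligodendrocyte −0.62. With the granule neuron profile subtracted, P14 medians were: homeostatic microglia microglia −0.15, myelin oligodendrocyte 0.96. For members with at least 5 UMIs, P10 medians were: interferon interneuron −1.002 and oligodendrocyte −0.31, p53 targets granule neuron −0.52. For members with at least 5 UMIs, P14 medians were: reactive astroglia astroglia 1.30. With the intron length trend removed, P10 medians were: interferon interneuron −0.0081, mature granule neuron granule neuron 0.57, early granule neuron granule neuron −0.017, cell cycle progenitor −0.33 and interneuron −1.959, reactive astroglia astroglia −0.026, cholesterol synthesis astroglia 0.048, disease-associated microglia microglia −0.076, homeostatic microglia microglia −0.27, myelin oligodendrocyte −0.75, U5 and tri-snRNP interneuron −0.40 and granule neuron −0.33, p53 targets granule neuron −0.12, ATF4 and integrated stress response targets granule neuron −0.091, ferroptosis and iron handling granule neuron −0.31. With the intron length trend removed, genes called numbered: endothelial 1, fibroblast 1. With the intron length trend removed, WT P14 over P10 medians were: mature granule neuron granule neuron 0.41, early granule neuron granule neuron −0.17, cell cycle progenitor −0.079, myelin oligodendrocyte −1.51, disease-associated microglia microglia 0.043, homeostatic microglia microglia −0.051. At the same cluster makeup, P14 medians were: interferon granule neuron 0.72 and oligodendrocyte 0.53, mature granule neuron granule neuron 0.13, early granule neuron granule neuron −0.033, Shh response granule neuron −0.045, cell cycle progenitor −0.12, Bergmann glia astroglia −0.27, myelin oligodendrocyte 1.20, cholesterol synthesis oligodendrocyte 0.51, U5 and tri-snRNP granule neuron −0.053, p53 targets granule neuron −0.011. For granule neurons without cluster 10, P14 medians were: mature granule neuron granule neuron 1.79, early granule neuron granule neuron −0.10, Shh response granule neuron −0.089, p53 targets granule neuron 0.016. For oligodendrocytes without cluster 11, P14 medians were: interferon oligodendrocyte 2.09. Without thinning, Eftud2 shares (%) in granule neurons were: P10 WT 25.7, P10 cKO 33.1, P14 WT 22.3, P14 cKO 33.5.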

Other observations

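These genes come from a ranking at P14 alone that was added after the data were seen, and were picked from it by their values. In P14 microglia Il12b, a cytokine subunit, was at 0 CPM in WT and 21.5 CPM in cKO, and Acod1, which makes itaconate, at 2.27 and 26.9 CPM. Ifi202b, a gene whose expression differs between inbred strains, was at 21.9 CPM in microglia of P14 WT and 0 CPM in those of P14 cKO, and reads can be shared within its gene family. In P14 leukocytes the natural killer cell genes Xcl1, Ncr1 and Klre1 were at 229, 160 and 207 CPM in WT and at 0 CPM in cKO, and Ccl5 was at 1238 and 19.3 CPM. This class held 102 cells in WT and 30 in cKO, and a count of 0 sets a limit of 3 counts only. Its leukocyte markers summed to 22432 and 75463 CPM. A different mix of leukocytes was not told apart from a change within them. In P14 fibroblasts Bglap, the bone protein osteocalcin, was at 455 and 0.452 CPM. In P14 endothelial cells the chemokine gene Ccl4 was at 3.50 and 143 CPM. In P14 astroglia Ptgds, a prostaglandin synthase abundant in oligodendrocytes and the coverings of the brain, was at 11.4 and 276 CPM, and Myoc at 0.687 and 48.7 CPM.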
